A study of Mus musculus with 12 samples.

How the data were processed

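The series profiled bone marrow-derived macrophages of female FVB mice after 4 h with IFNG (200 units/mL) or IL4 (40 ng/mL). Per the labels' protocols, about 10% of each cell preparation was lysed for total mRNA, and the remaining lysate was run on a 5 to 50% sucrose gradient from which messages with more than 3 ribosomes were collected as polysome-associated mRNA. Libraries were made with the SmartSeq2 method, per the labels. The group and the replicate number of each library were read from its labels, which spell the first cytokine both IFNG and INFG. This gave 4 groups of 3 libraries, 12 in all. The labels do not say whether replicates came from separate animals or cultures, so p-values measure the spread between these samples, which may be technical.

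Each file gives a whole-number read count per gene symbol, deposited without normalization, per the file headers and the values. A further column holds log2 values that the authors made by TMM scaling, per the file headers. Those values were given for 11006 of the 19549 features, all with a read in at least 7 of the 12 libraries, while the others had reads in at most 6. They matched log2 CPM computed from the counts with the offset of limma's voom and 1 constant size per library, with a largest relative deviation of 3.93e-14. Those sizes, solved from the author values, were 0.993 to 1.01 times the TMM-scaled library sizes used here. HISAT2, HISAT, limma and the build mm10 are named, without versions, per the submitters' processing notes. The counter, its strand setting and the gene annotation are not given in the sources used here. Reads of overlapping genes and antisense partners therefore cannot be told apart, and genes that share reads with close copies, among them the Gbp and H2 families, Tgtp1 and the histones, are uncertain. A total of 830 features join several gene symbols and held 7.57 to 12.3% of the reads of a library. Of the feature names, 17995 were symbols of the RefSeq annotation of GRCm38, the assembly that mm10 stands for, and positions come from that annotation.

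The counts were analysed in R 4.3.3 with edgeR 4.0.16. Features were kept with filterByExpr over the 4 groups, which left 10421, of which 673 were joined features. Libraries were scaled with TMM, and 1 quasi-likelihood model with 4 groups, no covariates and robust dispersion was fitted to all 12 libraries, so that the groups share 1 estimate of the spread. The 4 comparisons were IFNG against IL4 in total mRNA, the same in polysome-associated mRNA, their difference (an interaction term, here called polysome association), and polysome-associated against total mRNA averaged over the polarizations. All adjusted p-values are Benjamini-Hochberg values with a threshold of 0.05. Gene levels are CPM (counts on TMM-scaled libraries, as edgeR's cpm gives them), given as mean ± SD of 3 libraries. Where a gene had no count in 1 group, the fold is a lower bound computed against 3 counts over the group. Where it had 1 to 3 counts, the ratio is given with its 95% counting interval. These intervals and floors cover counting error only.

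Gene lists were fixed before the data were examined, as were the comparisons, the tests, the rule for named genes and the first group of other settings given below. They were interferon-induced GTPases, interferon-stimulated antiviral genes, MHC class I and class II presentation, JAK-STAT and IRF regulators, chemokines, inflammatory mediators, alternative activation genes, polyamine metabolism, fatty acid oxidation, glycolysis, cholesterol biosynthesis, oxidative phosphorylation, ribosomal proteins, translation factors with terminal oligopyrimidine (TOP) ends, integrated stress response, immediate early and mRNA decay regulators, iron handling, lysosome and cathepsins, MNK-eIF4E and mTOR pathway, and cell cycle. Marker lists covered macrophages, neutrophils, dendritic cells, B cells, T and NK cells, stromal cells, megakaryocytes, erythroid cells, and mast cells with basophils. Lists with at least 3 tested members were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. Lists of mitochondrially encoded and of nuclear noncoding transcripts had 0 members among the features analysed here. The named genes of a comparison were the 8 with the largest positive and the 8 with the largest negative fold change among called genes of at least 10 CPM in 1 group and with no overlap between groups, leaving out predicted genes, which removed 1 in total mRNA and 1 in polysome-associated against total mRNA. Up to 4 called members of each list followed, or up to 2 by level where none was called, and a fixed set of 18 polarization genes. Lars2, the replication-dependent histones and the features without an author log2 value were singled out after their values were seen.

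Total counts ranged from 2563955 to 22014162 per library, and 3 counts corresponded to 0.184 to 1.13 CPM. The median standard error of the log2 fold change was 0.49 in total mRNA, 0.50 in polysome-associated mRNA, 0.70 for polysome association and 0.35 for polysome-associated against total mRNA. The edgeR test was tested on simulated data of 10421 features with 67 genes changed by 1, 67 by 2 and 66 by 3 on the log2 scale. It recovered 0%, 44.8% and 87.9% of them in total mRNA, and 7.46%, 44.8% and 93.9% in polysome-associated mRNA. The recovered shares were 2.99%, 19.4% and 65.2% for polysome association, and 20.9%, 83.6% and 98.5% for polysome-associated against total mRNA. It called 5, 3, 2 and 5 unchanged genes in these comparisons, and camera called 0 of 20 random lists in each. The simulated genes were drawn independently, so the random lists cannot show how often camera calls lists of correlated genes. The simulated libraries were independent as well, so the recovered shares do not reflect that both fractions came from the same cells. In polysome association the estimated correlation was 0.475 for ribosomal proteins and 0.493 for oxidative phosphorylation.

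Replicate numbers recur in the 4 groups. Deviations from the group mean correlated across 7039 genes between same-numbered libraries of the polarizations, with r = 0.53, 0.14 and 0.75 in total mRNA and 0.26, 0.16 and 0.36 in polysome-associated mRNA. Of the 12 libraries, 12 had their highest correlation with a library of another group at their own number. For number 2 that was the other fraction of the same polarization, so this count alone does not show pairing across polarizations. The numbers were taken to pair the libraries across polarizations within a fraction, on the correlations given first. Between same-numbered libraries r was -0.10, -0.10 and -0.18 for IFNG total with IL4 polysome. It was -0.12, 0.097 and 0.0092 for IFNG polysome with IL4 total. Whether they stand for shared cells or shared processing is not given in the labels. The main model, fixed in advance, does not use this pairing. Between the fractions of 1 polarization, which the protocol says came from the same cells, r was 0.25, 0.43 and -0.08 with IFNG and 0.01, 0.38 and 0.02 with IL4. No pair of libraries of a group agreed within counting noise.

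The other settings fixed in advance were DESeq2 1.42.0, limma-voom, DESeq2 size factors, upper-quartile factors, no filter on low counts, a filter at a mean of 10 CPM, a replicate block, a block within each polarization, the 6 libraries of 1 fraction alone, a regression of polysome on total log2 CPM per gene (with and without a block), and leaving out each library. Chosen after seeing the data were leaving Lars2 out of the counts, leaving out both polysome libraries numbered 3 and thinning every library to the smallest total. The features with an author log2 value and leaving out joined features were also chosen then. Ranges given for lists over their alternatives are those of camera at the preset correlation, so they leave out the estimated correlation.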

Results

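Macrophages grown from mouse bone marrow were polarized for 4 h with IFNG (interferon gamma), which drives classical activation, or with IL4 (interleukin 4), which drives alternative activation. From each preparation, total mRNA and the mRNA found with more than 3 ribosomes were sequenced, which gave 4 groups of 3 libraries. No unpolarized cells were among the samples, so each difference is IFNG relative to IL4. The total counts were 22014162, 10443200 and 11817228 in the IFNG total libraries and 15051290, 16603339 and 12348819 in the IL4 total libraries. They were 8789480, 4898268 and 3189688 in the IFNG polysome libraries and 5546605, 2563955 and 2746716 in the IL4 polysome libraries. A single gene, Lars2 (chromosome 9, 123366927 to 123462675 of mm10), singled out after its values were seen, took 14.6 ± 13.8% of the counts of the IFNG polysome libraries and 11.7 ± 6.48% of the IL4 polysome libraries (mean ± SD, n = 3). Its share was 1.24 ± 0.837% with IFNG and 1.17 ± 0.285% with IL4 in total mRNA. Whether these reads came from the Lars2 message was not tested. Levels below are CPM (library-scaled counts), mean ± SD of 3 libraries, with adjusted p from edgeR for genes and from camera of limma for lists.

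The comparison of IFNG with IL4 in total mRNA asks how the transcriptomes of the polarized cells differed. Genes of the interferon response were higher with IFNG. Irf1 (chromosome 11, 53770014 to 53778374), a transcription factor of the interferon response, measured 396 ± 152 CPM with IFNG and 21.5 ± 9.58 CPM with IL4 (log2 fold change 4.20, SE 0.57, adjusted p = 1.52e-05). Gbp2 (chromosome 3, 142620663 to 142638008), a GTPase of the defence against intracellular pathogens, measured 935 ± 238 against 1.13 ± 0.425 CPM (log2 fold change 9.68, SE 0.64). Gbp6 measured 48.9 ± 26.0 CPM with IFNG and had 0 counts with IL4, at least 706-fold higher. The chemokine Cxcl9 (chromosome 5, 92321331 to 92328079), which attracts T cells, measured 4885 ± 2287 CPM with IFNG against 2 counts over the IL4 libraries (ratio 108400, 95% counting interval 30010 to 895000).

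All 19 tested interferon-induced GTPases were higher with IFNG, and 19 adjusted over the list alone (camera adjusted p = 4.04e-57; adjusted p = 0.00816 with an estimated correlation). Of the interferon-stimulated antiviral genes, 26 of 28 were higher and 27 adjusted over the list alone (camera adjusted p = 9.83e-53), among them Rsad2 at 806 ± 424 against 4.58 ± 1.54 CPM. All 14 genes of MHC class I presentation were higher, and 14 adjusted over the list alone (camera adjusted p = 4.49e-15), with Tap1, a peptide transporter, at 628 ± 270 against 42.0 ± 7.12 CPM. For MHC class II presentation 7 of 11 were higher, and 8 were higher and 1 lower adjusted over the list alone (camera adjusted p = 5.77e-05; adjusted p = 0.11 with an estimated correlation). Ciita, the class II master regulator, measured 30.2 ± 20.3 against 1.07 ± 1.21 CPM. Of 27 inflammatory mediators 22 were higher and 25 adjusted over the list alone (camera adjusted p = 6.7e-40), with Nos2, the inducible nitric oxide synthase, at 103 ± 37.0 against 0.242 ± 0.419 CPM. Of the JAK-STAT and IRF regulators 10 were higher and 3 lower of 25, and 15 and 3 adjusted over the list alone (camera adjusted p = 4.33e-07; adjusted p = 0.0682 with an estimated correlation). Chemokines went both ways, with 8 higher and 5 lower of 22, and 9 and 6 adjusted over the list alone (camera adjusted p = 3.71e-05; adjusted p = 0.064 with an estimated correlation). Beside these groups, 5 of 13 macrophage markers and 2 of 3 dendritic cell markers were higher with IFNG, and 7 and 2 adjusted over each list alone (camera adjusted p = 3.71e-05 and 0.000899). The macrophage marker Fcgr1, a receptor for antibodies, measured 430 ± 53.6 against 20.8 ± 5.996 CPM. The dendritic cell marker Xcr1 measured 9.42 ± 6.45 against 0.182 ± 0.181 CPM. Only 3 of the 10 dendritic cell markers listed had enough reads to be tested. Of these Clec9a had 0 counts with IL4, so it was tested only through the IFNG libraries. The dendritic cell list therefore says little about dendritic cells. Of 5 neutrophil markers 1 was higher, and 3 adjusted over the list alone, although the list did not pass (camera adjusted p = 0.126). The called marker S100a9, a calcium-binding protein, measured 6.10 ± 8.10 CPM with IFNG against 1 count with IL4 (ratio 273, 95% counting interval 48.5 to 10850). The features given an author log2 value exclude Clec9a and include 631 features not tested otherwise, so the members of the dendritic cell list changed. With them the list had a median log2 fold change of 0.86 and no longer passed (camera adjusted p = 0.121, and 0.000529 to 0.121 over its alternatives).

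Genes of alternative activation were lower with IFNG than with IL4. Retnla (chromosome 16, 48842609 to 48844461), a secreted protein of IL4-treated macrophages, measured 0.154 ± 0.176 CPM with IFNG and 4370 ± 1920 CPM with IL4 (log2 fold change -14.77, SE 0.98, adjusted p = 1.2e-09). Arg1 (chromosome 10, 24915207 to 24927470), which breaks down arginine, measured 0.772 ± 0.777 against 688 ± 460 CPM. Mrc1 (chromosome 2, 14229414 to 14332023), the mannose receptor, measured 86.7 ± 32.2 against 550 ± 180 CPM (adjusted p = 0.000323). Of 38 alternative activation genes, 22 were lower and 6 higher, and 23 and 8 adjusted over the list alone (camera adjusted p = 1.97e-14; adjusted p = 0.00121 with an estimated correlation). Ccl22, a chemokine of that list, measured 7.11 ± 1.01 against 12.7 ± 8.33 CPM and did not pass (adjusted p = 0.377).

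Cell cycle and cholesterol genes were also lower with IFNG. Of 25 cell cycle genes 15 were lower and 1 higher, and 20 and 2 adjusted over the list alone (camera adjusted p = 3.93e-09; adjusted p = 0.064 with an estimated correlation). The mitotic kinase Plk1 measured 8.37 ± 4.91 against 67.7 ± 29.8 CPM, while the higher member was cyclin Ccnd2, at 947 ± 651 against 36.6 ± 9.32 CPM. Of 21 cholesterol biosynthesis genes 8 were lower, and 11 adjusted over the list alone (camera adjusted p = 4.78e-08; adjusted p = 0.064 with an estimated correlation), with the demethylase Cyp51 at 3.58 ± 1.69 against 23.5 ± 4.31 CPM. Of 14 glycolysis genes 5 were higher, and 5 adjusted over the list alone (camera adjusted p = 0.000899; adjusted p = 0.17 with an estimated correlation), with Pfkfb3, an enzyme that speeds glycolysis, at 44.5 ± 12.9 against 5.63 ± 1.52 CPM. Of 27 immediate early and mRNA decay regulators 7 were higher and 1 lower, and 9 and 2 adjusted over the list alone (camera adjusted p = 0.000422; adjusted p = 0.17 with an estimated correlation). None of the 71 ribosomal protein genes was called by edgeR, and 0 adjusted over the list alone, although the list had a median log2 fold change of -0.37 (camera adjusted p = 0.00368; adjusted p = 0.679 with an estimated correlation). The iron importer Tfrc, of the iron handling list, measured 20.7 ± 12.7 against 175 ± 72.7 CPM (adjusted p = 0.00016).

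The lists that did not pass in total mRNA, by camera adjusted p, were oxidative phosphorylation (0.0591), polyamine metabolism (0.0591, and 0.0233 with a replicate block), fatty acid oxidation (0.0892), integrated stress response (0.111) and translation factors with TOP ends (0.214). Stromal markers (0.758), lysosome and cathepsins (0.758), the MNK-eIF4E and mTOR pathway (0.758) and iron handling (0.844) did not pass either. The single tested B cell and megakaryocyte markers were not called over all genes, nor were the 2 T and NK cell markers. Adjusted over the list alone, the megakaryocyte marker was lower (log2 fold change -2.81), 1 T and NK cell marker was higher and 0 B cell markers passed. Mknk2, a kinase of the translation factor eIF4E, measured 87.3 ± 39.6 against 90.0 ± 24.2 CPM (adjusted p = 0.976). In the MNK-eIF4E and mTOR list the median was 0.04, and the mean of -0.04 and the test had the opposite sign. Over all 10421 genes tested with edgeR, 738 were higher and 410 lower with IFNG. Without IFNG total replicate 2, the lower count was 202.

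The comparison in polysome-associated mRNA asks how the translatomes of the polarized cells differed. Interferon response genes were again higher with IFNG. Gbp2 measured 952 ± 339 against 1.53 ± 1.00 CPM (log2 fold change 9.33, SE 0.65, adjusted p = 4.44e-09). Nos2 measured 176 ± 51.9 CPM with IFNG and had 0 counts with IL4, at least 667-fold higher, and the chemokine Cxcl11 was at least 1052-fold higher. Retnla measured 0.270 ± 0.236 against 20767 ± 10469 CPM (log2 fold change -16.01, SE 1.01, adjusted p = 1.36e-09), and Mrc1 229 ± 83.7 against 2030 ± 624 CPM. Atf4, the transcription factor of the integrated stress response, measured 82.5 ± 18.7 against 17.2 ± 5.35 CPM (adjusted p = 0.000875), and Deptor, an inhibitor of mTOR, 0.716 ± 1.06 against 30.1 ± 7.74 CPM.

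By list, 18 of 19 GTPases (19 adjusted over the list alone; camera adjusted p = 2.71e-41), 25 of 28 antiviral genes (27 adjusted over the list alone; 6.45e-42), 11 of 14 MHC class I genes (14 adjusted over the list alone; 6.24e-12) and 18 of 27 inflammatory mediators (23 adjusted over the list alone; 4.57e-32) were higher with IFNG. For MHC class II 5 of 11 were higher, and 7 were higher and 1 lower adjusted over the list alone (camera adjusted p = 0.000802; adjusted p = 0.167 with an estimated correlation). JAK-STAT and IRF regulators had 10 higher and 3 lower of 25, and 14 and 3 adjusted over the list alone (camera adjusted p = 1.75e-05; adjusted p = 0.126 with an estimated correlation). Chemokines had 7 higher and 5 lower of 22, and 9 and 5 adjusted over the list alone (camera adjusted p = 0.00296; adjusted p = 0.144 with an estimated correlation). Macrophage markers had 7 of 13 higher, and 7 adjusted over the list alone (camera adjusted p = 0.000114). The dendritic cell markers, 3 tested of 10 listed, had 2 higher, and 2 adjusted over the list alone (camera adjusted p = 0.000802). With the features given an author log2 value the camera adjusted p was 0.0801 (0.000386 to 0.0801 over its alternatives). Clec9a had 0 counts with IL4 here too. Of 38 alternative activation genes 22 were lower and 5 higher, and 24 and 6 adjusted over the list alone (camera adjusted p = 4.22e-13; adjusted p = 0.00475 with an estimated correlation). Cell cycle genes had 13 lower and 1 higher of 25, and 18 and 2 adjusted over the list alone (camera adjusted p = 2.38e-07; adjusted p = 0.113 with an estimated correlation). Cholesterol genes had 10 lower of 21, and 15 adjusted over the list alone (camera adjusted p = 2.71e-07; adjusted p = 0.0977 with an estimated correlation). Glycolysis had 4 of 14 higher, and 6 adjusted over the list alone (camera adjusted p = 0.0013; adjusted p = 0.176 with an estimated correlation).

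Messages of the ribosome and of the respiratory chain were lower on polysomes with IFNG as lists. Of 71 ribosomal protein genes 5 were lower by edgeR and 0 adjusted over the list alone, with a median log2 fold change of -0.87 (camera adjusted p = 1.16e-08; adjusted p = 0.339 with an estimated correlation). Rps9, a protein of the small subunit, measured 735 ± 161 against 2378 ± 1720 CPM (log2 fold change -1.69, adjusted p = 0.0212), and its call was lost without IFNG polysome replicate 3 (0.0649) or IL4 polysome replicate 3 (0.236; 0.00439 to 0.395 over its alternatives). Of 67 oxidative phosphorylation genes 3 were lower and 0 adjusted over the list alone, with a median of -0.84 (camera adjusted p = 2.71e-07; adjusted p = 0.387 with an estimated correlation). Beside both lists, the Lars2 share ranged from 1.78% to 29.3% among the IFNG polysome libraries and from 5.15% to 18.1% among those of IL4. Polyamine metabolism had 2 of 12 lower, and 3 adjusted over the list alone (camera adjusted p = 0.00377; adjusted p = 0.0965 with an estimated correlation). Fatty acid oxidation had 3 of 19 lower, and 4 adjusted over the list alone (camera adjusted p = 0.0136; adjusted p = 0.113 with an estimated correlation). The integrated stress response list had 6 higher and 1 lower of 19, and 7 and 1 adjusted over the list alone (camera adjusted p = 0.0365; adjusted p = 0.402 with an estimated correlation). Immediate early and mRNA decay regulators had 6 higher and 1 lower of 27, and 6 and 1 adjusted over the list alone (camera adjusted p = 0.026; adjusted p = 0.401 with an estimated correlation). The stress response call was lost without IFNG polysome replicate 3 (0.117), IL4 polysome replicate 1 (0.0914) or IL4 polysome replicate 2 (0.154). It was also lost with the filter at a mean of 10 CPM (0.0872) and with thinned libraries (0.0672). The immediate early call was lost without IFNG polysome replicate 2 (0.076) or IL4 polysome replicate 1 (0.0682), and with the filter at 10 CPM (0.088). Over their alternatives at the preset correlation the camera adjusted p ranged from 0.00598 to 0.154 and from 0.00598 to 0.088.

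The lists that did not pass on polysomes, by camera adjusted p, were translation factors with TOP ends (0.0744), lysosome and cathepsins (0.384), stromal markers (0.463), iron handling (0.493), the MNK-eIF4E and mTOR pathway (0.771) and neutrophil markers (0.859). Within iron handling 4 of 12 were higher and 1 lower, and 4 and 2 adjusted over the list alone, with the iron exporter Slc40a1 at 52.3 ± 19.4 against 6.39 ± 3.48 CPM and Tfrc at 38.6 ± 8.34 against 363 ± 161 CPM. Over all 10421 genes tested with edgeR, 786 were higher and 686 lower with IFNG. The higher count was 498 without IL4 polysome replicate 2 and 504 without IL4 polysome replicate 3. The lower count was 356 without IFNG polysome replicate 2, 446 without IFNG polysome replicate 3, 443 without IL4 polysome replicate 2 and 356 without IL4 polysome replicate 3. Without IFNG polysome replicate 1 the majority turned, with 811 higher and 964 lower.

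Between the comparisons 583 genes were higher in both, 314 lower in both and 0 were called in opposite directions. Independent lists would share 55.7 and 27.0. Both fractions came from the same preparations, so a larger overlap was built into the design and the excess is no separate evidence. A further 251 genes were called in total mRNA alone and 575 on polysomes alone. Across 6984 genes of at least 10 CPM on average, which are not independent replicates, the log2 fold changes had Pearson r = 0.92 and Spearman rho = 0.80. Without IFNG total replicate 1, 1 gene was called in opposite directions, Tubb2b, a tubulin outside the rule for named genes and chosen after its values were seen. The number lower in both was 197 without IFNG polysome replicate 2 and 167 without IFNG total replicate 2.

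**Figure D1:**
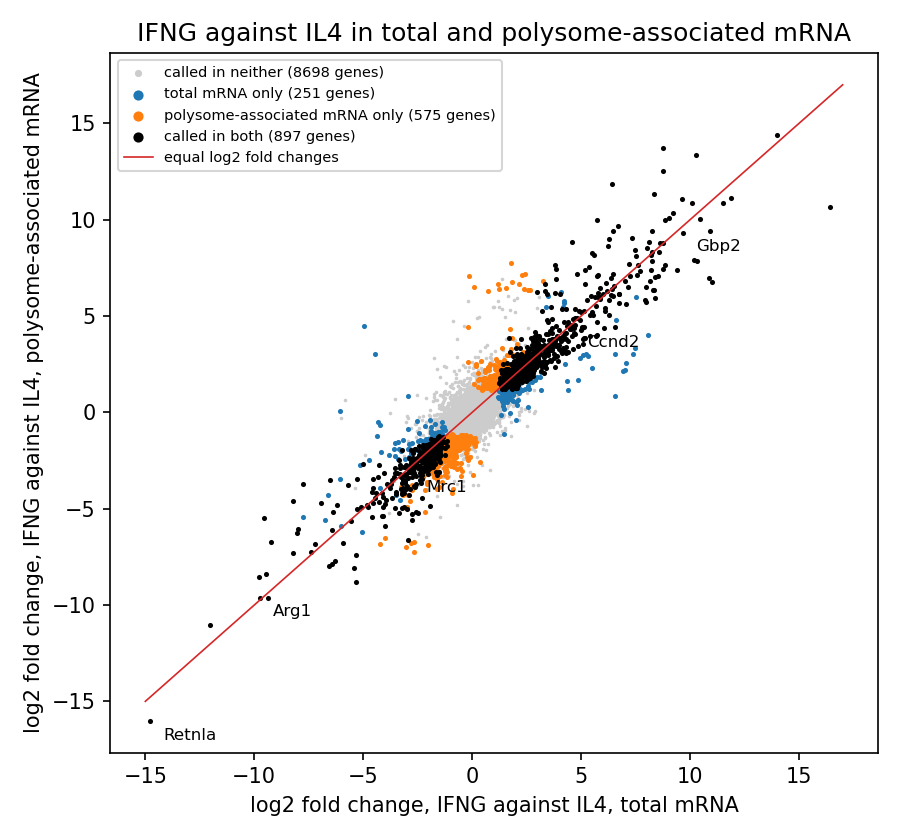
Log2 fold change of IFNG against IL4 for each of 10421 genes in total mRNA (x axis) and in polysome-associated mRNA (y axis). Black points were called in both, blue in total mRNA alone (251), orange on polysomes alone (575) and grey in neither, and the red line marks equal change.

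The test of polysome association asks whether IFNG and IL4 differed in polysome-associated mRNA beyond total mRNA. With edgeR 0 of 10421 genes were called higher and 0 lower. An unadjusted p under 0.05 was found for 176, fewer than the 5% of genes that chance would give. This number was 252 with a replicate block and 228 with a block within each polarization. The test may thus be conservative here, and the 0 calls do not show that polysome association was equal. The median standard error of 0.70 was the widest of the 4 comparisons. DESeq2 called 0 higher and 1 lower, and limma-voom 0 and 0. The smallest edgeR adjusted p was that of Cxcl9 (log2 fold change -5.77, SE 1.12, adjusted p = 0.378), which DESeq2 called (adjusted p = 0.0325). Cxcl9 had 37823 counts on polysomes and 169716 in total mRNA with IFNG, against 13 and 2 with IL4. Arg1 (log2 fold change 0.10, SE 1.22), Mrc1 (-0.48, SE 0.61) and Mknk2 (0.26, SE 0.59) each had an adjusted p of 1.

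As lists, ribosomal protein and oxidative phosphorylation messages were lower on polysomes with IFNG beyond their total mRNA. The camera adjusted p was 9.85e-08 for 71 ribosomal protein genes and 6.89e-09 for 67 oxidative phosphorylation genes, and the adjusted p with an estimated correlation was 0.729 and 0.702. No member of either was called by edgeR, and 0 adjusted over the list alone. Per preparation, the median ribosomal protein log2 CPM on polysomes minus that in total mRNA was -1.50, -2.48 and -3.64 with IFNG and -1.75, -1.42 and -2.04 with IL4. The IFNG preparation at -3.64 also had the highest Lars2 share on polysomes, 29.3%, and without that polysome library (IFNG polysome replicate 3) the ribosomal protein list no longer passed (adjusted p = 0.0601; 4.26e-16 to 0.0601 over its alternatives). Chemokines passed as well (median log2 fold change -0.28, camera adjusted p = 0.0391; adjusted p = 0.702 with an estimated correlation), with 0 of 22 called and 1, Cxcl9, lower adjusted over the list alone. That call was lost in 6 of the fits that leave out 1 library (7.74e-05 to 0.371 over its alternatives), and with genes of at least 10 CPM on average the list passed downward while its median was 0.03. No other list passed. Median, mean and test differed in sign for cell cycle genes (-0.09, -0.07, upward), glycolysis (-0.17, -0.03, upward) and inflammatory mediators (-0.16, 0.21, downward).

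**Figure D2:**
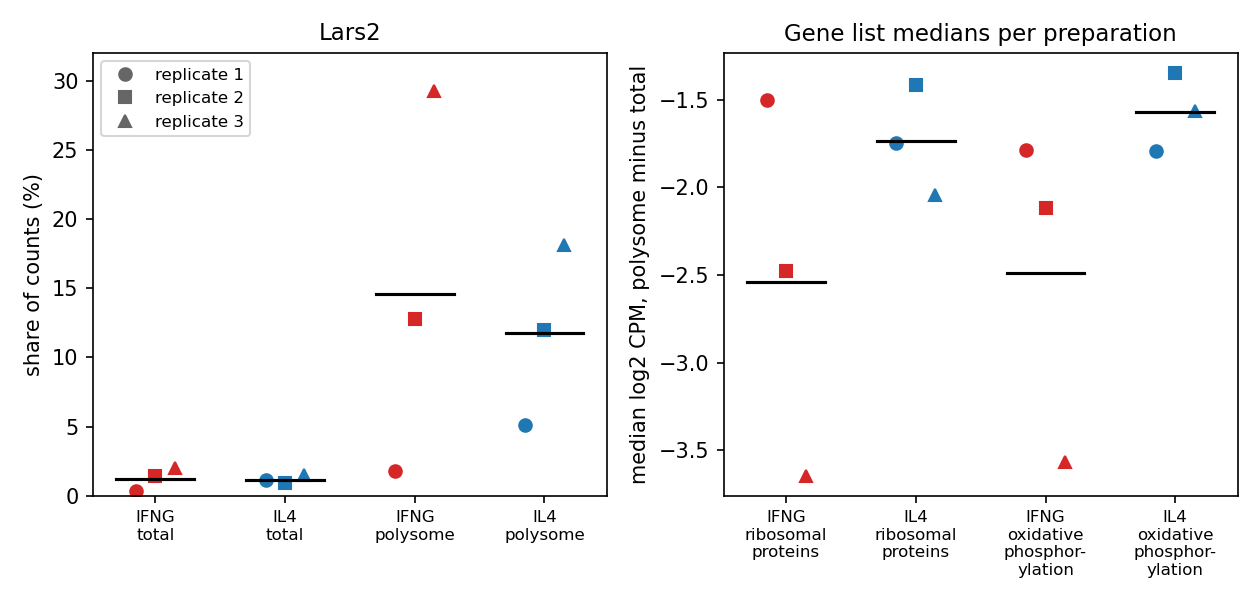
Left, share of counts (percent) taken by Lars2 in each library, and right, median log2 CPM on polysomes minus total mRNA of the ribosomal protein and oxidative phosphorylation genes in each preparation. Red marks IFNG, blue IL4, the marker shape the replicate number and the bar the mean of 3, and IFNG replicate 3 has the highest Lars2 share (29.3%) and the lowest ribosomal protein median (-3.64).

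The comparison of polysome-associated with total mRNA, averaged over the polarizations, asks which messages were over- or under-represented on polysomes relative to the composition of each library. Messages of ribosomal proteins, the respiratory chain and ferritin were lower on polysomes. Fth1 (chromosome 19, 9980600 to 9985111), the ferritin heavy chain, measured 1129 ± 1391 CPM on polysomes and 31988 ± 10732 CPM in total mRNA with IFNG, and 434 ± 239 against 21449 ± 5302 CPM with IL4 (log2 fold change -5.23, SE 0.55, adjusted p = 5.57e-07). Ftl1 (chromosome 7, 45457944 to 45459886), the light chain, measured 1963 ± 1574 against 58596 ± 23170 CPM with IFNG. Rpl41 (chromosome 10, 128548110 to 128549168), a small protein of the large ribosomal subunit, measured 86.8 ± 35.4 against 1852 ± 447 CPM with IFNG and 71.4 ± 22.5 against 2590 ± 549 CPM with IL4 (log2 fold change -4.79, SE 0.35). The ATP synthase subunit Atp5e (log2 fold change -4.01, SE 0.34) and the antizyme Oaz1, which limits polyamines (-4.18, SE 0.44), were lower too. Among the genes higher on polysomes, the ubiquitin ligases Mib1 (log2 fold change 2.67, SE 0.31) and Herc2 (2.64, SE 0.31) had some of the largest changes, and the RNA-binding protein Hnrnpa2b1 measured 1426 ± 863 against 462 ± 187 CPM with IFNG and 4022 ± 2032 against 466 ± 9.87 CPM with IL4.

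Of 71 ribosomal protein genes 65 were lower on polysomes and 0 higher, and 66 were lower adjusted over the list alone (median log2 fold change -1.96, camera adjusted p = 2.21e-25; adjusted p = 0.813 with an estimated correlation). Of 67 oxidative phosphorylation genes 55 were lower and 2 higher, and 56 and 2 adjusted over the list alone (median -1.83, camera adjusted p = 3.28e-19; adjusted p = 0.813 with an estimated correlation). Beside these lists, Lars2 was higher on polysomes (log2 fold change 3.44, SE 0.57, adjusted p = 7.82e-05). No other list passed. Translation factors with TOP ends had 4 higher and 8 lower of 19 (camera adjusted p = 0.576), from Tpt1 (-2.39) to Eif3a (1.46). Alternative activation genes had 13 higher and 3 lower of 38 (0.391), MHC class II 1 higher and 7 lower of 11 (0.347), and the MNK-eIF4E and mTOR pathway 9 higher and 4 lower of 26 (0.664). Mrc1 (log2 fold change 1.64, SE 0.31) was higher on polysomes, and Atf4 (-2.41, SE 0.30) lower. Medians and means or tests differed in sign for cholesterol biosynthesis, the dendritic and neutrophil markers, immediate early genes, antiviral genes and JAK-STAT and IRF regulators, none of which passed. Over all 10421 genes tested with edgeR, 2353 were higher and 2675 lower on polysomes. With upper-quartile factors the majority turned, with 2683 higher and 2449 lower.

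**Figure D3:**
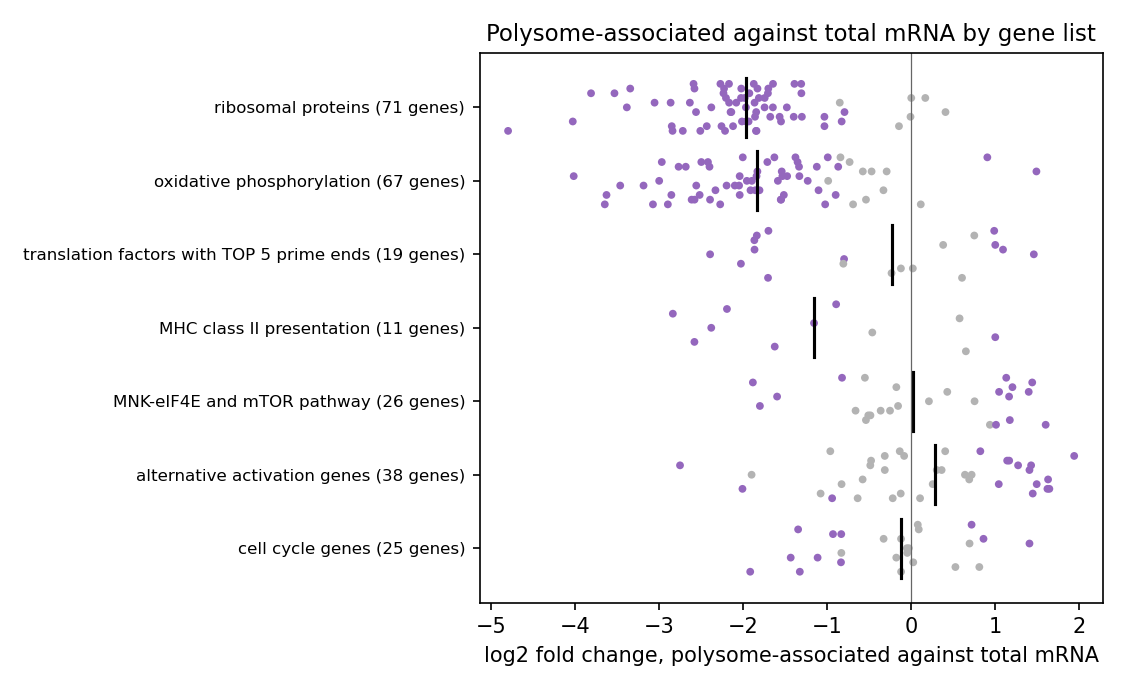
Log2 fold change of polysome-associated against total mRNA for each tested member of 7 gene lists. Purple points passed the test, grey points did not, and the black bar is the list median, lowest for ribosomal proteins (-1.96) and oxidative phosphorylation (-1.83).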

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

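The spread between preparations, the counts without Lars2, the ribosomal protein median relative to all genes, the thinned counts, the TOP-end comparison and the other splits of the libraries were tests chosen only after the results were seen, and the omission of single libraries was not.

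The interaction test of camera, at its preset correlation, passed for 3 lists in polysome association between IFNG and IL4: ribosomal proteins (adjusted p = 9.85e-08), oxidative phosphorylation (adjusted p = 6.89e-09) and chemokines (adjusted p = 0.0391). All 3 were lost with an estimated correlation (adjusted p = 0.729, 0.702 and 0.702), and 0 of their members were called by edgeR. The chemokine result was lost without IFNG polysome replicate 1 (0.312), IFNG polysome replicate 2 (0.0621), IFNG total replicate 3 (0.371), IL4 polysome replicate 1 (0.251), IL4 polysome replicate 2 (0.104) or IL4 total replicate 3 (0.262), and its median ran from -0.58 to 0.03 over all alternatives.

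Ribosomal protein and oxidative phosphorylation messages had negative medians for polysome association (-0.53 and -0.54), with 0 of 71 and 0 of 67 genes called and the list calls lost with an estimated correlation (adjusted p = 0.729 and 0.702). Leaving Lars2 out of the counts scales the other genes of a library alike, so the adjusted p of 1.56e-07 for ribosomal proteins decides nothing about what goes with a high Lars2 share. Without IFNG polysome replicate 3 the adjusted p for ribosomal proteins was 0.0601 (4.26e-16 to 0.0601 over the alternatives at the preset correlation) with a median of -0.20. Single omissions gave medians from -1.04 to -0.20. The oxidative phosphorylation median ran from -1.25 to -0.20 over its alternatives. The camera adjusted p of that list was at most 0.0228 at the preset correlation, but 0.702 with an estimated correlation. In 2 of the 3 IFNG preparations the ribosomal protein median of polysome minus total lay below every IL4 preparation, so the groups overlapped. For replicate number 1 it was higher with IFNG (-1.499) than with IL4 (-1.748). The oxidative phosphorylation medians were -1.786, -2.116 and -3.564 with IFNG and -1.795, -1.348 and -1.565 with IL4, so these groups overlapped too. A single library, the spread between preparations and the Lars2 share therefore stay open beside an effect of polarization.

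Ribosomal protein and oxidative phosphorylation messages were lower in polysome-associated than in total mRNA. With every library thinned to the smallest total, 62 of 70 ribosomal protein genes and 55 of 67 oxidative phosphorylation genes were lower, which argues against depth. Counts taken by Lars2 lower all other genes of a library alike, and the ribosomal protein median lay at -2.01 relative to all genes, which argues against that share by itself as the whole cause. Translation factors with TOP ends had a median of -0.23 (SD 1.28) against -1.96 for ribosomal proteins. They ran from Tpt1 (-2.39) to Eif3a (1.46), so having such ends did not always go with a lower level on polysomes. Message length, which bears on how many ribosomes a message can hold, was not analysed here. It may differ between these lists, so the comparison cannot decide about TOP ends. Both TOP ends and message length stay open.

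Other splits of the same libraries were counted for each comparison. In total mRNA (1148 genes called, highest other split 0) and in polysome-associated mRNA (1472, highest other 0), 1 of 10 splits gave as many genes, the real one, and 10 splits are too few for a share under 0.05. For polysome association (0 genes, highest other 0) 10 of 10 splits gave as many, and the splits are again too few. For polysome-associated against total mRNA (5028 genes), 1 of 100 splits gave as many, the real one, and the highest other, which parts fewer pairs of libraries from the same cells, called 2311. Of all 32 splits that part every such pair, 1 gave as many, the real one (share 0.0312), and the highest of the others called 1306. That share is the smallest that 32 splits can give, and it argues against chance only if the 6 preparations are independent. If same-numbered preparations are linked across polarizations, the splits that keep this are too few for a share under 0.05.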

How the results depend on the processing

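Leaving out both polysome libraries numbered 3, leaving Lars2 out, thinning, the author features and leaving out joined features were tests chosen only after the data were seen. Counts of called genes in the 4 comparisons stayed within 1.5 times of those reported under the alternatives run, except those given here and the single omissions named beside each count. Of the counts that set total against polysome-associated mRNA, 3 moved further under single omissions: genes lower in both (197 and 167) and genes called in opposite directions (1). With both polysome libraries numbered 3 left out, which leaves 2 per polysome group, 432 genes were higher and 258 lower in polysome-associated mRNA. For polysome association DESeq2 called 1 gene lower (Cxcl9), and without a filter on low counts 1 was higher (Tubb2b) and 4 lower (Cxcl9, Hist1h2ag, Hist1h2ah and Hist1h3a), where the cause was not tested. These genes other than Cxcl9 lie outside the rule and were chosen after their values were seen. Leaving out 1 library at a time gave 507 to 791 higher and 202 to 461 lower in total mRNA, 498 to 894 higher and 356 to 964 lower in polysome-associated mRNA, 0 to 0 in both directions for polysome association, and 1900 to 2538 higher and 2309 to 2794 lower for polysome-associated against total mRNA. With a replicate block 850 and 584 genes were called in total mRNA, 911 and 896 in polysome-associated mRNA, 0 and 0 for polysome association and 2514 and 2734 for polysome-associated against total mRNA. The regression of polysome on total log2 CPM called 0 and 0 genes (1249 at an unadjusted p under 0.05, more than the 5% of genes that chance would give). The named-gene values were also counted under the other settings fixed in advance, single omissions aside. Of these, 3096 kept their side of the threshold, 29 fell short of it and 24 newly passed. A further 63 stayed uncalled and moved by at least their standard error. The 3096 were called values that also kept their direction, and uncalled values, of either direction, that moved by less than their standard error. Under single omissions the same counts were 4482, 191, 16 and 39, and under the added alternatives 1872, 38, 10 and 15. None reversed. Upper-quartile factors moved the median log2 fold change of all genes from 0.04 to 0.15 for polysome-associated against total mRNA (2683 genes higher and 2449 lower) and from 0.04 to -0.09 in total mRNA. Leaving Lars2 out moved it from -0.06 to 0.06 in polysome-associated mRNA and from 0.04 to -0.09 for polysome-associated against total mRNA (1899 and 2945).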

Other observations

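The histone sum, its omission of single libraries, its ratios per preparation and the cell cycle comparison were tests chosen only after the results were seen.

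Replication-dependent histone messages, which lack poly(A) tails in dividing cells, were lower with IFNG than with IL4 on polysomes. This family was chosen after its values were seen. How far the SmartSeq2 libraries captured messages without such tails was not tested, so the histone levels and ratios given here may not follow the amounts of these messages. Of 52 tested histone features 43 were lower with IFNG on polysomes and 9 in total mRNA by edgeR, with 0 higher in either. The summed counts of 59 features measured 675 ± 357 CPM with IFNG and 10864 ± 9322 CPM with IL4 on polysomes (log2 fold change -4.01, SE 0.64, adjusted p = 0.000133, n = 3), and 626 ± 289 against 2373 ± 926 CPM in total mRNA (-1.92, SE 0.59, adjusted p = 0.0348). Without IL4 polysome replicate 3 the IL4 polysome mean was 5629 CPM and the polysome result -3.06 (SE 0.57, adjusted p = 0.00144; 9.53e-05 to 0.00193 over the single omissions). The total mRNA call was lost without IFNG total replicate 1 (0.141), IFNG total replicate 2 (0.145), IL4 total replicate 1 (0.128) or IL4 total replicate 3 (0.0614), and ran from 0.0155 to 0.145 over the single omissions.

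Of the tested genes 46 had no author log2 value, and those named here were chosen after their values were seen. Having reads in at most 6 of the 12 libraries is what sets these genes apart, so that they differ between groups follows from how they were selected. Il12b, a subunit of interleukin 12, measured 7.94 ± 2.47 CPM with IFNG and had 0 counts in all 6 IL4 libraries, at least 122-fold higher in total mRNA. The GTPase Gbp2b was at least 272-fold higher. Msx3, a homeobox gene, had 0 counts in all 6 IFNG libraries and measured 54.8 ± 27.3 CPM with IL4, at least 668-fold lower with IFNG, and Ccl17, a chemokine of IL4-treated macrophages, was at least 40.2-fold lower.

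A hypothesis is that histone messages were lower on polysomes with IFNG beyond their total mRNA, although 0 of 52 features passed that test with edgeR (20 at an unadjusted p under 0.05). Only without a filter on low counts did edgeR call histone features in this test, Hist1h2ag, Hist1h2ah and Hist1h3a, all lower. The summed counts had an interaction log2 fold change of -2.09 (SE 0.81, adjusted p = 1) and did not pass either, and since how reads that match several copies were counted is not given in the sources used here, sharing between copies stays open. The ratio of polysome to total histone CPM was 0.936, 1.10 and 1.12 in IFNG preparations 1, 2 and 3 and 1.05, 5.40 and 8.96 in those of IL4, lower with IFNG in 3 of 3 same-numbered pairs. Without IL4 polysome replicate 3 the interaction was -1.14 (SE 0.75), so a single library may account for part of it. The cell cycle list had a median interaction of -0.0855 on the log2 scale, and a smaller share of cycling cells with IFNG cannot be told apart from the other explanations while the histone shift depends on that library.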
